A study of Drosophila melanogaster with 2 samples.

How the data were processed

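Chromatin immunoprecipitation followed by sequencing was carried out on whole embryos of Drosophila melanogaster collected 0 to 24 hours after egg laying, males and females together. The flies carried a transgene for CG7786 fused at its C terminus to enhanced green fluorescent protein (eGFP), per the labels. The labels differ on the antibody: the description names one against GFP, while the antibody field names CG7786 as the target, so which of them was used is not settled here. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The set holds 2 libraries of 1 group, labelled biological replicates 2 and 3. How separate the 2 collections were beyond that label is not given in the sources used here.

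The authors deposited 8 peak lists, 4 on each of the genome builds dm6 and dm3. Per the text that goes with each library, a relaxed list of peaks and background was called from the alignments of each replicate and from the pooled alignments, each time against 1 control alignment. The authors then derived the optimal list of the irreproducible discovery rate procedure (IDR) from the relaxed lists of replicate 2, replicate 3 and the pool. The aligner, the peak caller, the IDR threshold and all versions are not given in the sources used here. The control was not analysed here.

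Each list deposited by the authors gives a signal value per peak, a score on the caller's own scale that is the authors' and not a read count. It was used only to rank, describe or filter peaks within a list. Each list deposited by the authors also gives a −log10 q-value. In the dm6 IDR list every peak has the same −log10 q of 3.91, so this column could not rank peaks. The number of reads per library is not given in the sources used here, so the depth is unknown and no interval that needs it was computed. Each relaxed list ends at 30000 entries whatever the depth. The dm6 IDR list was checked against the pooled list: its 4045 entries are the 4045 pooled entries with the highest signal value. Of its intervals, 4 are listed 2 times with different summits, and were kept.

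Positions are given 1-based on dm6. All dm6 peaks lay within the lengths of arms 2L, 2R, 3L, 3R, 4 and X of the Release 6 genome sequence used here. Genes, transcripts and transposable elements came from the Ensembl release 115 annotation of the same assembly, with 13945 protein-coding genes on these arms. The dm3 lists were described on their own and no coordinate was converted.

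Replicates were compared through the top N peaks of each relaxed list, with N the size of the IDR list. A summit within 200 bp counted as shared, and the chance level came from 1000 circular shifts of a list along each arm (one-sided). The signal values of the replicates at the IDR peaks were compared by Spearman's rho across peaks, with no p because peaks are not replicates. A peak was TSS-proximal when its summit lay within 500 bp of any annotated transcription start site (TSS) and distal otherwise. Distal summits were put in the first of these classes that applied: coding exon, 5' UTR, 3' UTR, other exon, intron, intergenic. Shares were set against 1000 random placements on the same arm (two-sided), and median signal values of proximal and distal peaks against 100000 permutations (two-sided). Densities per arm carry a 95% interval from 1000 bootstrap draws of 500 kb blocks.

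For 32 gene lists fixed before the data were examined, the share of members with a TSS-proximal peak was set against all other protein-coding genes. The test was Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over the lists. A gene counted when any of its annotated TSSs lay within 500 bp of a summit. A summit near the TSSs of several genes counted for each of them, while the test takes genes as independent. Genes with more TSSs had more chances to count, and the lists were not matched on TSS number. A further count used any peak in the gene span, the gene body plus 2000 bp upstream, against 10000 random lists of the same size and gene length deciles, adjusted in the same way. Of the names in the lists, 11 were matched through their current symbol and 1, a non-coding gene, stayed unmatched. The prefix used for accessory gland proteins also took in Acp1, Acp65Aa and Acph-1, which are not accessory gland genes.

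Sequence was read in 200 bp windows centred on summits. Each window had 1 control window off the peaks, on the same arm, of the same TSS class and within 2 percentage points of its GC content. TSS-proximal controls were not matched on distance to the TSS. Of all summits, 45.6% lay within 250 bp of a TSS against 7.52% of random placements, and 55.3% within 500 bp against 13.6%. Contrasts at TSS-proximal peaks may therefore partly set positions nearer a TSS against positions farther from it. Distal controls were not matched further on genomic class. They could lie in coding exons, which held 0.22% of summits against 13.9% of random placements. Contrasts at distal peaks may therefore partly set non-coding against coding sequence. Presence of 17 fixed motifs and of all 32896 8-mers, each on both strands, was compared by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over motifs and over 8-mers at 0.05. The share of windows with the PAR bZIP site was also followed along 5 equal bins of the IDR list, with exact binomial 95% intervals and a permutation test of its Spearman correlation with signal. Intervals over peaks or genes cover counting error only, because both replicates are already merged in the IDR list.

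The genes named are CG7786; genes with a TSS within 1000 bp of the 20 strongest summits; up to 4 members of each list in order of the signal value of their strongest TSS-proximal peak; the 5 genes with the most peaks in their span; and the nearest gene of the 5 strongest distal peaks. Of the 8-mers, the 10 with the smallest p are named. This rule, the gene lists, the motifs and the tests were set before the data were examined. Alternatives were other summit distances, other N, other TSS windows, only protein-coding TSSs, only genes that share no TSS window, the gene body alone, other window sizes, flanking sequence as control, other control draws, other bootstrap blocks, the 2022 strongest peaks, the top of the pooled list, the list of each replicate alone, and the dm3 lists.

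The statistics were tested on simulated data. Of 20 random 8-mers planted in 4% of 2022 windows, 20 were called, of 20 planted in 2% of windows, 20, and of 20 planted in 1%, 5. Between control windows split at random, with nothing planted, 0 of 32896 8-mers were called. Such a split does not cover imperfect matching of controls to summits. Of 6400 simulated gene lists at the share of all 13945 genes, 3 were called. Of as many at 2 times that share, 48.9% were called, and at 3 times that share, 93.7%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and blastn 2.17.0.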

Results

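CG7786 is an uncharacterised Drosophila gene whose product is a predicted basic leucine zipper (bZIP) transcription factor of the PAR type. Its eGFP fusion was mapped on the chromatin of whole embryos aged 0 to 24 hours, a mixture of all tissues and embryonic stages. The data are 2 libraries of 1 group, replicates 2 and 3, with no second condition to compare. The comparisons are therefore between the replicates, between the peaks and chance, and among classes of peaks, genes and sequences. The authors' IDR list on dm6 held 4045 peaks, 101 to 605 bp wide with a median of 404 bp, covering 1.48 Mb. Their signal values, the authors' score, ran from 79.5 to 2909 with a median of 130.1. Read numbers are unknown.

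The first question is how far the replicates repeat each other. Of the 4045 strongest peaks of replicate 2, 3142 (77.7%) had a summit among the 4045 strongest of replicate 3 within 200 bp. Circular shifts gave 1.20% on average and 2.00% at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Random entries of the other list, a chance level added after the data were seen, gave 14.6% on average and 16.5% at most. Of the IDR peaks, 85.8% had a summit in the top list of replicate 2, 91.2% in that of replicate 3 and 77.5% in both. The authors drew the IDR list from both replicates, so these shares describe that choice too. Across the 4037 IDR peaks that overlap an entry of both relaxed lists, Spearman's rho between the signal values of the replicates was 0.778. The same regions led both libraries: the 20 strongest IDR peaks all ranked 20 or better in replicate 2 and 22 or better in replicate 3.

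**Figure D1:**
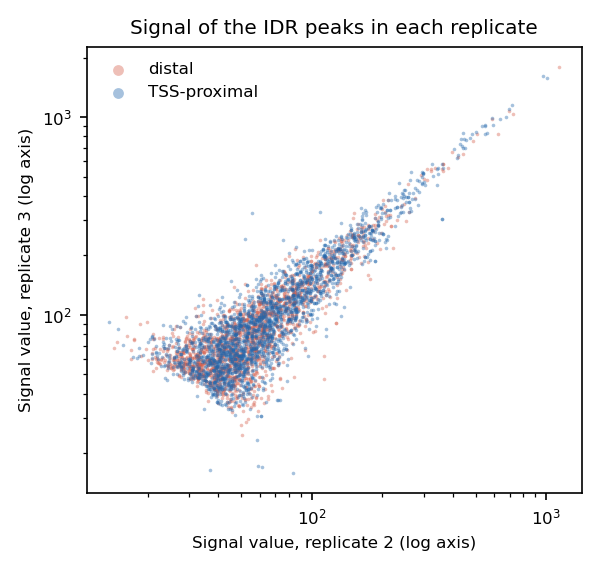
Signal value of each IDR peak in replicate 2 (x) and replicate 3 (y), both on log axes, with 1 point per peak for the 4037 peaks found in both relaxed lists; blue points are TSS-proximal and red points distal. The strongest peaks lie in a narrow band, and the scatter widens towards low signal values.

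The strongest peak lay at 2L:480864-481319 (dm6) in an intron of ush, which encodes a Friend-of-GATA cofactor, 1369 bp from the nearest protein-coding TSS, that of the zinc finger factor gene cbt. Its signal value was 2909, and it ranked 1 in both replicates. The peak at 3L:19590413-19590808, 96 bp from the TSS of CG14100, had a signal value of 2576, and that at X:2703669-2704106, 36 bp from the TSS of Ugalt, a UDP-galactose transporter gene, had 2572. They were followed by px at 2R:22514104-22514498 (1863) and by the Polycomb group gene ph-p at X:2137156-2137565 (1778). Of the 20 strongest peaks, 14 were TSS-proximal, 5 lay in introns and 1 was intergenic. Within 1000 bp of 15 of them lay the TSS of a protein-coding gene. Apart from those named, the nearest such genes were the kinase gene Lk6, the chromodomain protein gene Chro, CG1888, mRpL41, CG9663, PNPase, larp, Shc, Pal1, Art3 and CenG1A, with signal values between 1343 and 1747. The peaks at Art3 (1367) and CenG1A (1343) also lay 141 and 386 bp from the TSSs of mRpS10 and mRpS23. The 5 strongest distal peaks were the ush intron peak, those in introns of CG11050 (2L:6612504-6612912, 1747), Lk6 (3R:11760846-11761248, 1747) and CG9663 (2L:3301948-3302552, 1555), and an intergenic peak 11914 bp from the nearest protein-coding TSS, that of CG13323 (2R:13035152-13035525, 1437).

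Promoters took the larger part of the peaks. Of the 4045 summits, 2237 lay within 500 bp of a TSS, or 55.3% (95% exact interval 53.8 to 56.8%) against 13.6% of random placements, a 4.07-fold excess. Introns held 1287 summits, 31.8% against 39.6% at random, and intergenic sequence 436, 10.8% against 27.1%. Coding exons away from any TSS held 9 summits, 0.22% against 13.9% at random, and 3' UTRs 27, 0.67% against 4.44%. Each of these 5 shares differed from random placement with a two-sided permutation p of 0.002, the smallest that 1000 placements can give. Summits in 5' UTRs (18) and other exons (31) did not (permutation p = 0.23 and p = 0.83). Coding exons held 1.19% of summits in the replicate 2 list, and with a 1000 bp TSS window 5' UTRs held 0.124% against 0.337% at random (permutation p = 0.028). TSS-proximal peaks were also stronger, with a median signal value of 136.2 (quartiles 101.5 and 211.8) against 122.9 (95.6 and 180.5) for the 1808 distal peaks. The difference of 13.4 had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. It was 9.10 in the replicate 3 list and 3.62 in the replicate 2 list, each on its own scale.

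**Figure D2:**
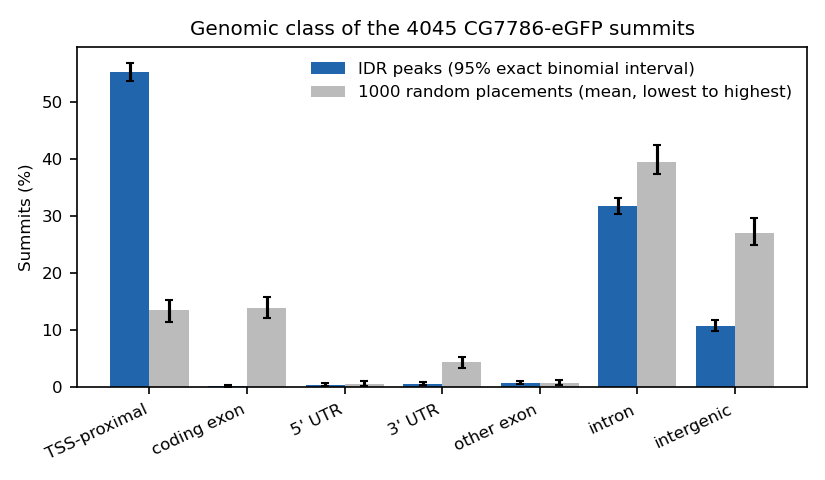
Share of IDR summits (y, percent) in each genomic class (x), with 95% exact binomial intervals, beside the mean of 1000 random placements on the same arms with their lowest and highest values. TSS-proximal summits make up 55.3% against 13.6% at random, and coding exons 0.22% against 13.9%.

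Peaks were spread over all large arms. Density was 33.6 peaks per Mb on the X chromosome (95% interval 28.7 to 38.6), 32.7 on 2L, 29.7 on 3R, 28.7 on 2R and 28.1 on 3L. The small, largely heterochromatic chromosome 4 had 18 peaks, or 13.4 per Mb (11.5 to 16.0). That interval rests on very few 500 kb blocks, because the arm is 1348131 bp long, and is likely too narrow. X density over autosomal density was 1.13, with an interval of 0.942 to 1.33 that includes equality. Of 2196 X-linked genes 18.9% had a TSS peak, against 19.6% of 11669 genes on the large autosomal arms, a difference that was not detected (odds ratio 0.955, Fisher's exact p = 0.45).

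In all, 2715 of 13945 protein-coding genes (19.5%) had a TSS-proximal peak at any of their TSSs. A summit shared by neighbouring genes counted for each of them, although the test takes genes as independent. Of the 7926 genes outside the ribosomal protein list that share no TSS window, 10.3% had a peak. The list comparisons were not matched on the number of TSSs per gene. Of the 32 lists 6 were higher than other genes and 3 lower. Cytoplasmic ribosomal protein genes had the largest odds ratio of the 32 lists, with 55 of 92 members (59.8%, 95% exact interval 49.0 to 69.9%) against 19.2% of other genes. Their odds ratio was 6.25 with a Benjamini-Hochberg adjusted Fisher's exact p of 5.39e-16. RpL7 (summit at 2L:10201039, signal value 607.1), RpS27 (3R:25247523, 601.4), RpS20 (470.2) and RpL23A (441.4) carried their strongest peaks. Mitochondrial ribosomal protein genes reached 26 of 73 (odds ratio 2.30, adjusted Fisher's exact p = 0.00812), led by mRpL41 (1574), mRpS10 (1367), mRpS23 (1343) and mRpL23 (629.1). Many of these genes share a promoter region with a neighbour: of the 13 whose TSS windows touch no other gene, 0 had a peak, and the call was narrowly lost among the 2022 strongest peaks at a similar odds ratio (2.24, adjusted Fisher's exact p = 0.05002). Translation factor genes stood at 18 of 52 (odds ratio 2.20, adjusted Fisher's exact p = 0.0444), with eIF6 (1271), eIF3c (357.0), eIF4EHP (307.2) and eIF3h (295.4) the strongest.

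Of the chromatin and Polycomb or Trithorax group genes, 17 of 34 had a peak at any of their TSSs (odds ratio 4.16, adjusted Fisher's exact p = 4.90e-04). The strongest were ph-p (1778), Trl, which encodes the GAGA factor (431.3), the insulator protein gene Cp190 (286.4) and the chromatin remodeller gene brm (268.8). Notch pathway genes reached 10 of 22 (odds ratio 3.46, adjusted Fisher's exact p = 0.0228), among them aph-1 (313.3), numb (257.0), E(spl)m3-HLH (201.8) and N itself (124.4). Cell cycle genes reached 12 of 31 (odds ratio 2.62, adjusted Fisher's exact p = 0.0444), with the E2F partner gene Dp (571.7), dup (291.0), aurA (231.5) and polo (144.6). The calls of the Notch, cell cycle and translation factor lists did not hold in the replicate 3 list alone (odds ratios 2.38, 2.64 and 2.03, adjusted Fisher's exact p = 0.15, 0.0503 and 0.0751), among the fewer genes that share no TSS window (3.22, 2.14 and 1.71, adjusted p = 0.35, 0.59 and 0.62) or for the 2022 strongest peaks (1.25, 1.53 and 2.135, adjusted p = 1, 0.83 and 0.19). The first 2 did not with a 250 bp TSS window either (2.45 and 2.504, adjusted Fisher's exact p = 0.18 and 0.0882). Those of ribosomal protein and chromatin genes held in all 4, and the odds ratio of chromatin genes was 6.85 in the replicate 2 list and 8.62 among genes that share no TSS window.

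Odorant and gustatory receptor genes and the accessory gland and testis list had TSS peaks less often, in a comparison not matched on TSS number. None of 59 odorant receptor genes had a TSS peak (95% exact interval up to 6.06%, odds ratio 0.0346 with a continuity correction, adjusted Fisher's exact p = 6.11e-05). Only Gr63a (101.5) of 60 gustatory receptor genes (odds ratio 0.0698, adjusted Fisher's exact p = 4.90e-04) and Sfp26Ad (205.3) of 59 accessory gland and testis genes (odds ratio 0.0710, adjusted p = 5.62e-04) did. Among genes that share no TSS window these latter calls were lost with 0 of 42 and 0 of 30 genes (odds ratios 0.100 and 0.140, adjusted Fisher's exact p = 0.10 and 0.31), and the accessory gland call also for the 2022 strongest peaks (odds ratio 0.136, adjusted p = 0.0657). Chorion and vitelline genes, active in the ovary, had 0 of 18 (adjusted Fisher's exact p = 0.11, and 0.0484 with a 1000 bp TSS window).

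The patterning lists did not pass the threshold. TSS peaks were found at 1 of 14 genes of the gap list (bcd, the maternal anterior determinant, 146.3, and no other member). Of the 11 genes put in the pair-rule list, 2 had a TSS peak (bowl, 414.7, and hry, 82.5). The hry peak ranked 1749 in replicate 2 but 15295 in replicate 3. Segment polarity genes had 2 of 16 (nkd, 163.5, and smo, 97.7) and Hox genes 0 of 8. Proneural and neuroblast genes had 0 of 19 (adjusted Fisher's exact p = 0.11, and 0.0381 with a 1000 bp TSS window), and tracheal and epidermal as well as haemocyte and fat body genes 0 of 14 each (both adjusted p = 0.19). Among tissue lists, 1 of 20 neuronal function genes had a peak (elav, 459.8), 3 of 12 glial genes (moody, 759.0; Gli, 92.3; loco, 82.3) and 3 of 17 mesoderm regulators (Mef2, 129.3; Poxm, 99.6; htl, 84.8). The muscle list had 3 of 25 (Msp300, 899.5; sls, 414.7; Tm1, 87.4), the endoderm list 2 of 12 (fkh, 357.8; Hnf4, 99.1) and the germline list 2 of 11 (nanos, 198.7; tud, 85.2). Maternal and zygotic regulators had 4 of 18 (Sxl, 214.9; nanos; bcd; smg, 105.4). In the replicate 3 list the odds ratio of glial genes was 0.378 in place of 1.38. That of mesoderm regulators was 0.260 in place of 0.886, and that of the pair-rule list 0.416 in place of 0.919. For such short lists the intervals are wide: 0 of 8 Hox genes allows a share of up to 36.9%.

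The remaining lists also stayed below the threshold. The counts were 3 of 16 ecdysone response genes (Eip75B, 414.8; usp, 192.8; Hr78, 98.8), 7 of 28 Dpp, EGF and Hippo pathway genes (spi, 472.2, hpo, 350.8, Ras85D, 198.5, and aos, 113.8), and 3 of 23 immune genes (cact, 441.1; imd, 325.4; pll, 143.1). Heat shock and stress genes had 7 of 20, with Hsp83 (301.7), Hsp27 (293.2), Hsp26 (241.3) and Hsc70-4 (148.3). This list passed only among genes that share no TSS window (5 of 13, odds ratio 5.37, adjusted Fisher's exact p = 0.0499), and the Dpp, EGF and Hippo list only with a 1000 bp TSS window (odds ratio 3.48, adjusted p = 0.0109). Proteasome genes had 10 of 48 (Rpn5, 385.7; Rpn3, 239.7; Prosbeta1, 166.1; Rpn6, 162.5). Respiratory chain genes had 20 of 88 (ND-MWFE, 394.0; ND-ASHI, 295.1; COX6B, 248.1; COX5A, 227.4). Circadian clock genes had 3 of 12 (sgg, 575.5; dco, 130.4; vri, 123.8). Single replicates moved some odds ratios: that of heat shock genes was 1.39 in the replicate 3 list in place of 2.23, and in the replicate 2 list those of clock, ecdysone response and tracheal genes were 2.11, 1.92 and 0.702 in place of 1.38, 0.955 and 0.142. Of 18 bZIP factor genes, 7 had a TSS peak (odds ratio 2.64, adjusted Fisher's exact p = 0.17), the strongest at Atf3 (X:1275517, 1300), Irbp18 (412.1), cnc (205.8) and Xbp1 (147.9). The bZIP list passed the threshold with a 1000 bp TSS window (adjusted Fisher's exact p = 0.0367), in the replicate 2 list (0.0404) and among genes that share no TSS window (0.0300).

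**Figure D3:**
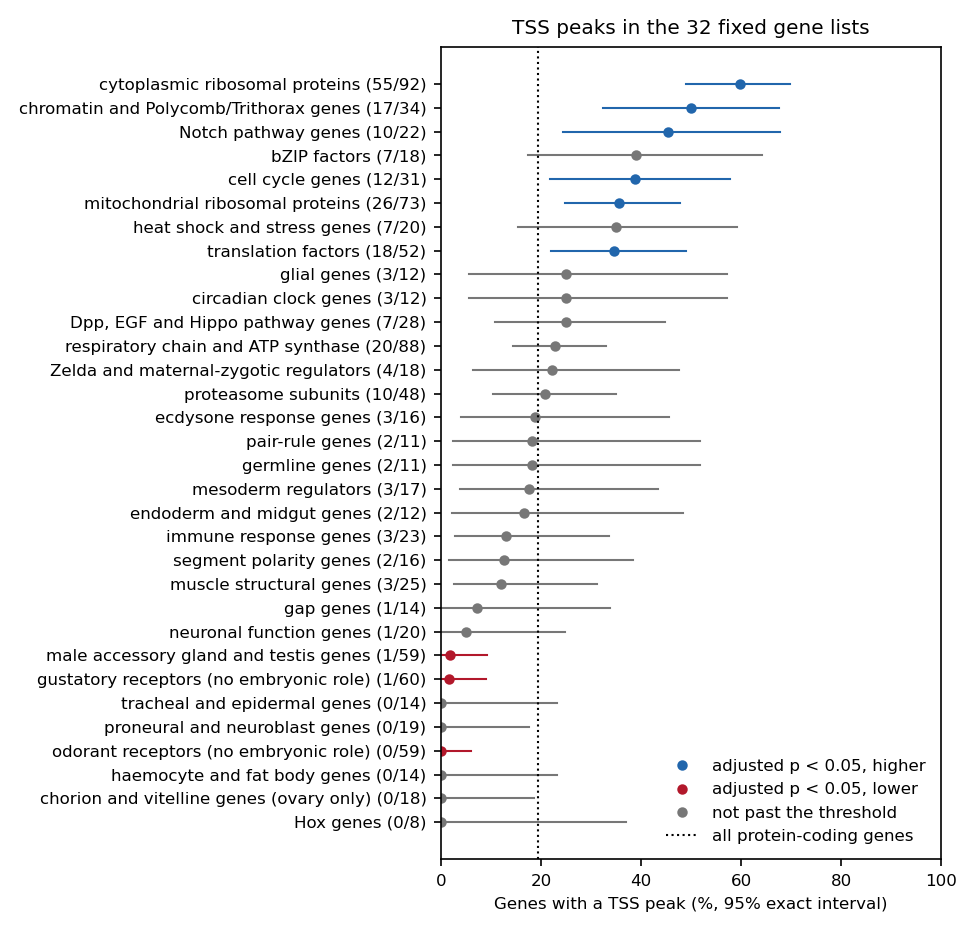
Share of genes with a TSS-proximal peak (x, percent) in each of the 32 gene lists (y, with counts), with 95% exact binomial intervals; the dotted line marks all protein-coding genes at 19.5%. Blue lists are higher and red lists lower at an adjusted p under 0.05, grey lists are not past it.

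A further count took any peak in the gene body or 2000 bp upstream. Of the 28 Dpp, EGF and Hippo pathway genes, 24 (85.7%) had a peak in their span, against 42.5% in random lists matched on gene length (permutation p = 2.00e-04 over random lists, two-sided, the smallest that 10000 lists can give, adjusted p = 0.0016). Ribosomal protein genes reached 57 of 92 (62.0% against 20.1%), mitochondrial ribosomal protein genes 32 of 73 (43.8% against 16.2%) and chromatin genes 24 of 34 (70.6% against 37.9%, adjusted permutation p = 0.00256). Neuronal function genes were lower, with 3 of 20 (against 47.6%, adjusted permutation p = 0.0219), as were odorant receptors, 2 of 59 (3.39% against 23.4%), and gustatory receptors, 4 of 60 (6.67% against 23.5%). Notch pathway genes, higher at TSSs, did not pass in this count (12 of 22, 54.5% against 32.9%, adjusted permutation p = 0.11). In the replicate 2 list they did (ratio to matched lists 1.80, adjusted permutation p = 0.0462), as did respiratory chain genes (1.59, adjusted p = 0.0462) and bZIP factor genes (1.956, adjusted p = 0.0320), the latter also for the 2022 strongest peaks (2.36, adjusted p = 0.0491). The neuronal call was lost in the replicate 2 list (ratio 0.423 in place of 0.315, adjusted permutation p = 0.0698) and, with the odorant receptor call, for the 2022 strongest peaks (ratios 0.499 and 0.252, adjusted permutation p = 0.46 and 0.10). With the gene body alone only the ribosomal protein and the Dpp, EGF and Hippo lists passed, while the ratios of mitochondrial ribosomal protein genes (2.52) and chromatin genes (1.94) stayed near those of the full span. The genes with the most peaks in their span were Raf, the kinase gene of the Ras pathway, and kirre. Raf had 14 peaks around its 48405 bp body (X:2295466-2343870), and kirre 14 over 394149 bp. They were followed by CG1677 with 12, shn, a Dpp pathway factor, with 12 over 58309 bp, and ush with 12 over 64341 bp. A span can hold other genes, as that of ush holds cbt, and summits at those genes counted too.

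The motif comparison asks which known sites mark the summits. The PAR bZIP site TTAYGTAA occurred in 79 of 4045 summit windows (1.95%) and 95 matched control windows (2.35%), an odds ratio of 0.828 (95% interval 0.613 to 1.12, adjusted Fisher's exact p = 0.43). Against 20 control draws in place of 1 it was 0.979 (0.769 to 1.23). The odds ratio was above 1 for the 2022 strongest peaks (1.34), in the replicate 3 list (1.20), in 400 bp windows (1.01) and against flanking sequence (1.35), never past the threshold. The other bZIP sites did not pass either: C/EBP TTGCGCAA 9 against 16, the mixed site TTRCGCAA 32 against 38, AP-1 78 against 56 and CRE TGACGTCA 13 against 10. The share with the PAR site in 5 bins of 809 peaks, from strongest to weakest, was 1.85, 2.35, 2.22, 1.36 and 1.98%, with no detected trend (Spearman's rho 0.0139, permutation p = 0.38, across peaks).

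Of the 17 fixed sites 4 were higher at summits. The DNA replication-related element TATCGATA occurred in 200 summit windows and 41 controls (odds ratio 5.08, adjusted Fisher's exact p = 9.00e-26), the M1BP site GGTCACAC in 108 and 35 (3.14, adjusted p = 3.12e-09), the CTCF site AGRKGGCGC in 81 and 20 (4.11, adjusted p = 3.12e-09) and the GAGA site in 156 and 110 (1.43, adjusted p = 0.0210). At TSS-proximal peaks the first of these sites was in 189 windows and 30 controls, and at distal peaks in 11 and 11. The M1BP site was in 102 and 30 at proximal peaks, and in 6 and 5 at distal peaks. CTCF sites were higher in both classes, with 37 and 11 at proximal and 44 and 9 at distal peaks. In 200 bp windows the E-box CATATG passed at distal peaks, with 154 and 107 (odds ratio 1.48, adjusted Fisher's exact p = 0.0260). The TSS-proximal controls were not matched on distance to the TSS. The distal controls could include coding exons, where few distal summits lay. The difference between TSS-proximal and distal peaks was not tested. The M1BP call was lost among the 2022 strongest peaks (odds ratio 1.45, adjusted Fisher's exact p = 0.48), and the GAGA call there (1.03), in 100 bp windows (1.02) and against flanking sequence (0.974). The GAGA odds ratio was 1.88 and 2.06 in the single replicates and 2.13 in 400 bp windows, past the threshold in each, while neither TSS-proximal (1.33) nor distal peaks (1.62) passed on their own (adjusted Fisher's exact p = 0.26 and 0.12). Other control draws, windows and peak sets gave odds ratios of 3.34 to 8.71 for the replication-related element and 2.92 to 10.1 for CTCF.

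**Figure D4:**
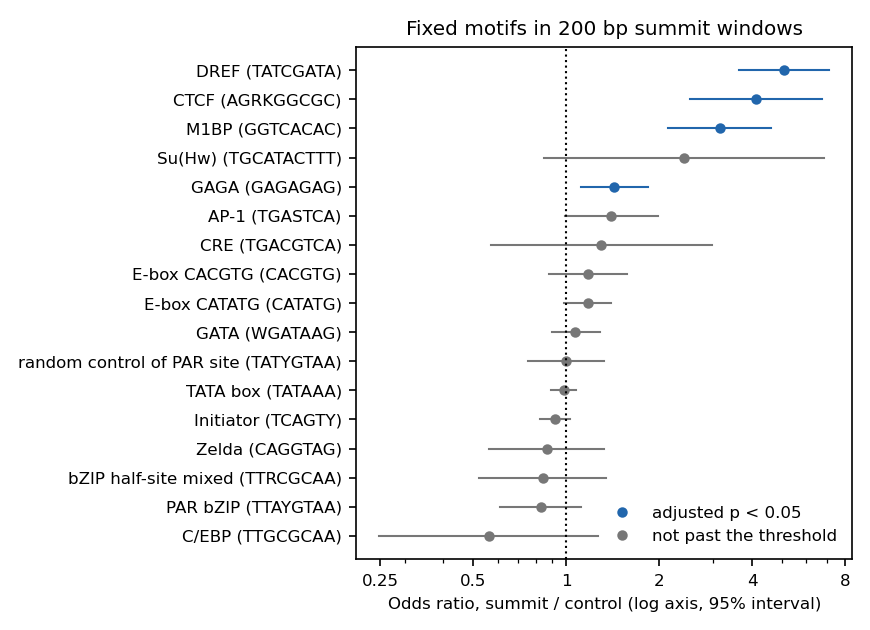
Odds ratio (x, log axis) of each of 17 fixed motifs (y) in 200 bp windows at 4045 summits against matched control windows, with 95% intervals; blue motifs pass an adjusted p of 0.05. The PAR bZIP site stands at 0.828 and the DREF site at 5.08.

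Of the remaining fixed sites none passed over all peaks in 200 bp windows: Zelda (39 against 45), CACGTG (101 against 86), CATATG (287 against 247), GATA (265 against 248), Su(Hw) (12 against 5), the TATA box (1165 against 1180), the initiator (710 against 760) and a scrambled PAR site (100 against 100). In 100 bp windows CATATG was higher (odds ratio 1.41, adjusted Fisher's exact p = 0.0233) and the TATA box lower (0.845, adjusted p = 0.0233). The initiator was lower for the same peaks with 1 of 2 redrawn sets of control windows (odds ratio 0.852, adjusted Fisher's exact p = 0.0179, against 0.898, adjusted p = 0.22, with the other) and in the replicate 3 list (0.861, adjusted p = 0.0335), and the TATA box and the scrambled site were higher against flanking sequence, which is not matched on GC content (1.58 and 1.91).

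Among all 32896 8-mers, 370 passed an adjusted p of 0.05, 292 of them more frequent at summits. Many of these calls depend on the control windows: for the same peaks 242 of the 370 passed again with another control draw, and 229 in a further draw. Words with the core CACTG, or CAGTG on the other strand, made up 82 of these 292 (28.1%), while they are 0.778% of all 8-mers. The 8-mer with the smallest p was CACTGTGC, in 197 summit windows (4.87%) and 23 controls (0.569%), with an odds ratio of 8.95 and an adjusted Fisher's exact p of 5.74e-32. CAACACTG (185 and 21), ACAGTGGG (154 and 16), CACAGTGG (181 and 29), TATCGATA (200 and 41), CCACTGTA (136 and 15), CACTGAGA (150 and 23), CACTGTAC (123 and 17), CAGCACTG (123 and 17) and ATCGATAG (205 and 58) completed the first 10. In 100 bp windows CCACTGTA and CACTGTAC did not pass (adjusted Fisher's exact p = 0.0584 and 0.0508). Overlapping 8-mers are not independent of each other. The classes of peaks led with different words: CAACACTG was in 172 of 2237 TSS-proximal windows and 12 controls, while CACTGAGA was in 113 of 1808 distal windows and 7 controls. This difference was not tested either. The distal controls could include coding exons, and the TSS-proximal controls were not matched on distance to the TSS.

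The CG7786 gene itself (FBgn0034096, 2R:16234358-16234936 on the minus strand, a single exon of 579 bp) had no IDR peak within 500 bp, and no entry of the pooled or replicate relaxed lists there. Within 10000 bp on either side lay 1 IDR peak with a signal value of 178.8, where a uniform spread gives 0.62.

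On dm3 the IDR list held 3954 peaks with the same median width of 404 bp, a median signal value of 131.9 and the same highest signal value of 2909. Arm 3R had 931 peaks on dm3 and 951 on dm6, X 772 and 792, 2L 750 and 769, 2R 710 and 726, 3L 771 and 789, and chromosome 4 had 17 and 18. On dm3, 3 peaks lay on unplaced sequence. The replicates shared 77.9% of their 3954 strongest dm3 peaks.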

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

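The replicate overlap, the excess of TSS-proximal peaks, the higher signal of TSS-proximal peaks and the absence of a detected X difference kept their direction and side of the threshold under every alternative run. The overlap ranged from 66.5 to 81.8%. The chance level from random entries of the other list, chosen after the data were seen, was 14.6%. The TSS-proximal share ranged from 45.6 to 65.4%. The number of dm3 peaks (3954) and the lack of a trend of the PAR site with rank also held. Ranking by q-value was not run because that column is constant in the IDR list. The top of the pooled list is the same set of peaks, so its changes come from newly drawn control windows: the DREF site had an odds ratio of 3.34 in place of 5.08, M1BP 4.24 in place of 3.14, and 229 of the 370 8-mers passed again.

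Several counts moved. Spearman's rho between replicates was 0.737 with the nearest summit within 200 bp and 0.802 over the 2022 strongest peaks. For these 2022 peaks, 4 gene lists passed at TSSs in place of 9, 2 motifs in place of 4 and 106 8-mers in place of 370. Of the calls lost there, M1BP fell to 1.45, GAGA to 1.03, the Notch list to 1.25 and the cell cycle list to 1.53, the mitochondrial ribosomal (2.24) and translation factor (2.135) lists kept their size, and the accessory gland list stood at 0.136. Among genes that share no TSS window 5 lists passed, with fewer genes tested, and mitochondrial ribosomal protein genes turned to an odds ratio of 0.316. With the gene body alone 2 lists passed in place of 7. 8-mers passing numbered 85 in 100 bp windows, 918 in 400 bp windows and 3915 against flanking sequence. Against these flanks, not matched on GC content, the TATA box had an odds ratio of 1.58, the scrambled PAR site 1.91, GAGA 0.974 and the PAR site 1.35. The PAR site also exceeded 1 for the 2022 strongest peaks (1.34) and in 400 bp windows (1.01), and was 0.939 to 1.20 in the single replicates, never past the threshold. The scrambled site, 1.00 in the report, was 0.867 for the 2022 strongest peaks, 0.915 for the top of the pooled list, 1.07 and 1.23 in 100 and 400 bp windows, 0.961 with another draw and 0.812 to 1.13 in the single replicates. The TATA box was 1.02 for the 2022 strongest peaks. The Dpp, EGF and Hippo list at TSSs had an odds ratio of 0.951 for those peaks and 0.905 to 1.40 in the single replicates. Where no construction is named, the cause was not tested. Lists, motifs and classes not given singly here changed direction in 57 of 314 values. Of the single values given, 267 kept direction and side of the threshold, 28 fell below it, 15 rose past it and 18 changed direction. Both tallies include the top of the pooled list, whose values for classes and gene lists could not change because its peaks are the same. The changes of direction include the scrambled site, which at 1.00 had no direction to change. A value that changed direction and also passed the threshold counts only as a change of direction. Depth is unknown, so its limits could not be set.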

Other observations

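Of 33 genes outside the ribosomal proteins that were taken as highly expressed, without expression values, 19 (57.6%) had a TSS-proximal peak. They include Fer1HCH and Fer2LCH, the ferritin chains, which share a peak (signal value 639.8), and the glycolytic genes Gapdh2 (436.1), Pgk (242.7), Eno (236.4), Tpi (105.1) and Pglym78 (92.4). The glycolytic genes Gapdh1 and Ald1 had none, nor did betaTub56D, Tctp and sesB. Of the 33 genes, 4 are also in the translation factor or heat shock lists. Of 290 tRNA genes, 15 (5.17%) had a summit within 500 bp. The examples were chosen after their values were seen.

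Below, the tests of repeat copies, of single replicates, of the orientation of words and of the PAR site were chosen after the result they bear on was seen. Those of highly expressed genes, tRNA genes and control windows were set down before their values were computed. The count among genes that share no TSS window was chosen before the data were examined, and its use as a test of neighbouring genes was set down after its value was seen. The design has no second group, so no biological explanation was tested for any of the 3 patterns.

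The enrichment of ribosomal protein promoters as an effect of neighbouring genes that share a peak is argued against by genes that share no TSS window, among which the odds ratio of the list was 8.71 (95% interval 4.16 to 18.2). Recovery of any highly transcribed chromatin stays open: tRNA genes had an odds ratio against protein-coding genes of 0.226 (0.124 to 0.379), but this cannot decide it. Reads from near-identical tRNA copies may be lost in mapping, and no expression values show that these genes were highly transcribed. Protein-coding genes could also count through several TSSs. A general recovery of promoters of highly transcribed protein-coding genes stays open as well. The highly expressed list had an odds ratio of 5.74 (2.73 to 12.4), beside 6.25 (4.04 to 9.78) for ribosomal proteins. As a hypothesis, the ribosomal protein peaks may thus go with promoter activity or openness in general. Expression values, accessibility and a GFP-only control were not used here.

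Within 150 bp of distal summits CACTGAGA occurred 156 times, and in 144 (92.3%, 95% exact interval 86.9 to 96.0%) it read towards the summit, at a median distance of 73 bp, while CACTGTGC did so in 26 of 161 (16.1%, 10.8 to 22.8%), and TSS-proximal peaks had similar shares, 43 of 50 (86.0%) and 23 of 118 (19.5%). Matched control windows held CACTGAGA 14 times, 28.6% reading to the centre (8.39 to 58.1%), but their centre is an arbitrary position, so this share decides nothing about base composition, which stays open. Without the 44 windows that blastn found similar to another, 142 of 154 occurrences (92.2%) read towards the summit. This argues against copies of a repeat similar enough for blastn to find as the whole source. Few occurrences lay in the 44 windows, and shorter or more diverged copies were not tested. A single library is argued against by 86.8% in the replicate 2 list and 92.9% in that of replicate 3. The promoter word CAACACTG read towards TSS-proximal summits in 93 of 235 occurrences (39.6%, 33.3 to 46.1%), at a median distance of 44.5 bp.

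The PAR site, the site predicted for this class of factor, was present at summits but with no detected excess over control windows. Summits set off from the site as the reason are argued against by 400 bp windows. In these, against 20 control draws, the odds ratio was 0.981 (95% interval 0.822 to 1.16). Only exact matches to the site were counted, so weaker forms of it were not tested. Dilution by weak peaks stays open: the 809 strongest peaks had 0.809 (0.446 to 1.36), with the site in only 15 windows, while the 2022 strongest had 1.16 (0.843 to 1.55), whose upper bound exceeds 1.5, a limit set after the main value was seen. Whether the fusion protein meets DNA through another sequence, through a partner, or is recovered at open chromatin cannot be settled from these lists, because no untagged or GFP-only pull-down was analysed here.

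Of the 4045 summits, 11 (0.272%) lay in annotated transposable elements, which cover 5.93% of these arms. Reads from repeated copies may be lost in mapping, and the aligner is not known. Mappable sequence was not set apart, so these values do not show that binding is rarer there.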
